A study of Homo sapiens with 54 samples.

How the data were processed

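Total RNA of WM266-4, an established human melanoma cell line, was measured on Affymetrix expression arrays after biotin labelling. The series holds 54 arrays in 18 groups of 3. In the inhibitor arm, 30 arrays cover DMSO, the RAF inhibitor LGX818 (encorafenib) at 0.05 uM, the MEK1/2 inhibitors trametinib at 0.003 uM and MEK162 (binimetinib) at 0.3 uM, and an ERK1/2 inhibitor at 0.2 uM that the labels do not name, each at 3 h and 24 h. In the shRNA arm, 24 arrays cover parental cells and cells carrying a non-targeting (NT) shRNA, the shRNA labelled shERK1 or the shRNA labelled shERK2, each at day 3 and day 7. The shRNAs were induced with 100 ng/ml doxycycline. The labels of the parental cells disagree on doxycycline: the treatment field names it, and the description says untreated. Every group has arrays lettered a, b and c. The labels do not state whether the 3 arrays of a group came from separate cultures, so every p measures the spread between those samples alone.

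The deposited values are log2 expression levels per probe set, made by the authors with RMA in the affy package per the submitters' processing notes, which give no versions. RMA corrects background, quantile normalises the arrays and summarises probes by median polish. The table holds 18989 probe sets. Of these, 62 are control probe sets, 17875 carry 1 gene symbol each, and 1052 are not listed in the probe table and were not used here. The probe set identifiers are gene based, so each gene has 1 value per array, and the choice among several probe sets of a gene, planned as an alternative, did not arise. The chip definition and genome build are not stated. Values ran from 2.51 to 14.8 log2, and array medians from 7.78 to 8.04. Arrays have no read depth; their number limits the precision.

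Quality was checked in R 4.3.3 from the correlation of arrays within groups, from principal components, and from the 3' minus 5' signal of the GAPDH and ACTB control probe sets, a measure of RNA degradation or incomplete labelling. Each array's mean correlation with the others of its group lay between 0.991 and 0.998, and 0 pairs of arrays held identical values.

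Genes were tested where the mean level of at least 1 group of the arm exceeded the median of all values, 7.86 log2. This left 9703 genes in the inhibitor arm and 9779 in the shRNA arm. For each arm, a linear model with 1 mean per group was fitted with limma 3.58.1 (lmFit, then eBayes with an intensity trend), which left 20 and 16 residual degrees of freedom. Errors printed beside log2 fold changes are the moderated standard errors (SE) of that fit. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. The comparisons were each inhibitor against DMSO of the same time, the difference of each inhibitor's effects at 24 h and 3 h, trametinib against MEK162, LGX818 and the ERK inhibitor against the mean of both MEK inhibitors, DMSO at 24 h against 3 h, each targeting shRNA against the NT shRNA of the same day, the shRNA labelled shERK2 against shERK1, the difference of each shRNA's effects at day 7 and day 3, NT shRNA against parental cells, and NT shRNA at day 7 against day 3.

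On simulated data of the same size, where 200 genes were shifted, the test recovered 86% of 100 genes shifted by 0.5 log2 and 100% of 100 shifted by 1 log2 in the LGX818 3 h comparison, and 8 of 194 calls were false (4.12%). In the shERK1 day 3 comparison it recovered 82% and 100%, with 12 of 194 calls false (6.19%).

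The comparisons, the test, the rule for named genes and 26 gene lists were fixed before the data were examined. The rule took the 10 largest rises and 10 largest falls (5 and 5 in comparisons between treatments, times or controls) among changed genes whose arrays in one group all lay beyond those of the other, up to 4 changed members of each list (the 2 largest rises and the 2 largest falls), and further genes fixed by name whether changed or not. Of these, MAPK3, DUSP6, SPRY4, CCND1, MYC, MITF and BCL2L11 are in the probe table, and the others are not reported here. BCL2L11 lay below the level filter and has no value in the tests. The level of the target of the shRNA labelled shERK2 is not analysed here. Members of the lists that the probe table does not name were not used. Lists with at least 3 tested members were tested against all other genes with camera in limma, with a preset correlation between genes of 0.01 and again with the correlation estimated (statmod 1.5.0), and with fry, which asks whether a list's genes move one way without comparing them with other genes. List p values were adjusted over the lists of a comparison. Of 26 lists, 24 could be tested; of the leukocyte and epithelial lists, fewer than 3 members passed the level filter in either arm.

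Because all inhibitors of one time share the DMSO arrays, genes changed alike by all 4 were set against the number from independent lists with the same counts and against 20 simulated data sets with no effect. Shared controls also raise correlations between fold changes, so these were set against simulated values. The effects of the shRNAs were compared with the mean effect of the 4 inhibitors at 24 h by Pearson r across the 9456 genes tested in both arms; these share no control arrays. Genes are not independent replicates, so no p is given for r.

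Alternatives were 1 fit of all 54 arrays, fits of only the groups compared, the array letter as a block, no level filter, arrays centred on their median, a minimum log2 fold change of 1, parental cells in place of NT shRNA, leaving out each array in turn, camera with an estimated correlation, and fry. Chosen after seeing the data were list tests against parental cells, list tests without arrays of raised 3' to 5' signal, counts of genes changed alike against both controls, and results without genes that differ between the controls. Each comparison was refitted under other splits of its arrays, all 10 for 3 against 3 and 100 drawn otherwise.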

Results

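WM266-4 melanoma cells were compared under 4 inhibitors of the RAF-MEK-ERK pathway after 3 h and 24 h, and after induction of shRNAs labelled shERK1 and shERK2 for 3 and 7 days, with 3 arrays per group. Fold changes are log2 with their SE, p values are adjusted within a comparison, and each gene named among the largest changes had all 3 treated arrays beyond all 3 control arrays. Values for inhibitors are given in the order LGX818, trametinib, MEK162 and ERK inhibitor unless stated. Their doses differed, so the values stand side by side. The values carry no detection calls, so a low level can be background, and a log2 difference from it is then a lower bound.

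Within 3 h, transcripts of feedback inhibitors of the pathway and of immediate early factors fell with every inhibitor. SPRY4, a sprouty inhibitor of receptor tyrosine kinase signalling, fell by 6.36, 6.08, 6.36 and 4.84 (SE 0.15), which is 82.2-, 67.6-, 82.2- and 28.7-fold (adjusted p = 4.80e-22, 3.04e-21, 4.79e-22 and 9.73e-19). DUSP6, a phosphatase of ERK, fell by 4.49, 2.69, 3.64 and 1.98 (SE 0.081). The cytokine LIF fell by 3.39, 3.15, 3.43 and 2.79, and the transcription factor MYC by 2.70, 1.99, 2.18 and 1.37 (SE 0.15). ID2, an inhibitor of helix-loop-helix transcription factors, had the largest rise with each inhibitor, at 3.22, 3.04, 3.12 and 2.61 (SE 0.12), 9.29- to 6.09-fold.

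The chemokines CXCL8 (-3.30, -3.20, -3.12 and -3.16) and CXCL1 (-2.78, -2.48, -2.75 and -2.29) also fell at 3 h. So did the immediate early factors EGR1 (-3.28, -3.18, -3.07 and -3.25) and EGR3 (-2.60, -2.84, -2.67 and -2.65), and SPRY1 (-3.23, -2.36, -2.84 and -1.95). Rises beside ID2 were those of the iron exporter SLC40A1 (2.18, 1.86, 2.23 and 1.60) and PPARGC1A, a coactivator of mitochondrial biogenesis (2.83-, 2.77-, 2.80- and 2.41-fold). CH25H, which hydroxylates cholesterol (1.57, 1.10, 1.36 and 1.12), the T-box factor EOMES (1.52, 1.28, 1.45 and 1.20) and LURAP1L (1.63, 1.18, 1.37 and 1.11) rose too. MITF, a regulator of melanocyte differentiation, rose by 0.47, 0.44, 0.48 and 0.37 (SE 0.048). The cyclin CCND1 fell by 0.56, 0.59, 0.65 and 0.58 (SE 0.068), and MAPK3, which encodes ERK1, did not pass the test (-0.053, 0.090, 0.051 and 0.014; adjusted p = 0.757, 0.525, 0.734 and 0.926). In all, 511, 494, 619 and 535 genes rose and 624, 600, 657 and 473 fell among 9703.

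All 9 tested ERK feedback regulators fell with each inhibitor at 3 h, overall and when adjusted over the list alone (median -1.99, -1.89, -2.01 and -1.46; adjusted p = 4.12e-31 to 2.70e-26). Of 9 MAPK activity genes, 7, 8, 7 and 7 fell (8, 8, 7 and 8 adjusted over the list alone) and 0 rose. Of 29 immediate early and AP-1 or ETS factors, 19, 21, 19 and 17 fell (21, 21, 20 and 20 over the list alone). Another 5, 4, 5 and 5 rose, among them the stress factor ATF3 (1.42, 1.23, 1.47 and 0.93). Ribosome biogenesis genes fell in 15, 12, 15 and 9 of 32 (20, 15, 19 and 10 over the list alone), with the nucleolar factor URB2 at -0.72, -0.81, -0.73 and -0.60. Among 11 inflammatory cytokines and NF-kB targets, 7, 7, 6 and 6 fell (7, 7, 8 and 8) and NFKBIA, an inhibitor of NF-kB, rose (0.47, 0.37, 0.56 and 0.47). Receptor tyrosine kinases and ligands fell in 5, 5, 7 and 5 of 13 (6, 6, 7 and 7), with the EGFR ligand TGFA at -1.18, -0.96, -1.14 and -0.93, and 1, 2, 2 and 1 rose, ERBB3 each time (0.23, 0.25, 0.19 and 0.17) and ERBB2 with trametinib and MEK162 (0.30 for both). Each of these 6 lists was called for each inhibitor and held with an estimated correlation, with adjusted p up to 0.0154.

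Of 17 melanocyte genes, 7, 6, 7 and 7 rose at 3 h (8, 8, 10 and 10 over the list alone), among them TYRP1, of melanin synthesis (0.65, 0.64, 0.55 and 0.55), and the channel gene TRPM1 (0.57, 0.64, 0.77 and 0.59), and 1, 1, 2 and 0 fell, MC1R with LGX818, trametinib and MEK162 (-0.54, -0.41 and -0.48). This call held for trametinib (adjusted p = 0.0405 with an estimated correlation) and was lost for LGX818, MEK162 and the ERK inhibitor (adjusted p = 0.0627, 0.0633 and 0.0782 with an estimated correlation). In the BCL2 family of 11, the pro-apoptotic BMF rose (1.64, 0.87, 1.63 and 0.98) while pro-apoptotic PMAIP1 (-1.64, -1.78, -1.82 and -1.48) and anti-apoptotic MCL1 (-0.95, -0.94, -0.91 and -0.79) fell. The family was called down with LGX818 (1 rose, 4 fell; adjusted p = 0.0102, and 0.047 with an estimated correlation), and the call was lost for trametinib and the ERK inhibitor (adjusted p = 0.106 and 0.0553 with an estimated correlation). Under trametinib its median was 0.0081 and its mean -0.16, so the sign rests on few members. Hypoxia genes were called down with LGX818, trametinib and MEK162 (4, 5 and 4 of 19 fell, with 5, 6 and 5 over the list alone, and 2, 1 and 0 rose; adjusted p = 0.0235, 0.00642 and 0.0143 with an estimated correlation). Their largest falls were those of the glycolytic regulator PFKFB4 (-1.71, -1.73 and -1.79) and ANGPTL4 (-1.29, -1.29 and -1.23).

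Among 21 p53 targets at 3 h, 7, 8 and 8 rose with LGX818, trametinib and MEK162 (11, 10 and 10 over the list alone). TP53INP1 stood at 0.88, 0.70 and 0.79 and the stress sensor SESN1 at 0.63, 0.61 and 0.65, while GDF15 fell by 1.90, 1.62 and 1.71. The call held for trametinib alone (adjusted p = 0.0509, 0.0491 and 0.105 with an estimated correlation). FOXO and PI3K-feedback genes rose in 8 of 20 with each of these inhibitors (10, 8 and 9 over the list alone), with the ubiquitin ligase FBXO32 at 0.66, 0.62 and 0.79. Another 2, 2 and 3 fell, among them TRIB2 (-0.99, -0.80 and -0.93) and IRS1 (-0.39, -0.37 and -0.70), and the call was lost (adjusted p = 0.0624, 0.114 and 0.173 with an estimated correlation). Mitotic genes were called up with LGX818, trametinib and the ERK inhibitor although 2, 1 and 1 of 36 rose, and that call was lost too (adjusted p = 0.377, 0.514 and 0.578 with an estimated correlation). The ERK inhibitor count of 1008 genes was 295 when only its group and DMSO were fitted, and 629, 646 and 631 without DMSO array a, DMSO array b and inhibitor array c. The last array had a GAPDH 3' minus 5' signal of 0.707, against 0.163 to 0.320 in control arrays. Without its array c, trametinib changed 721 genes.

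**Figure D1:**
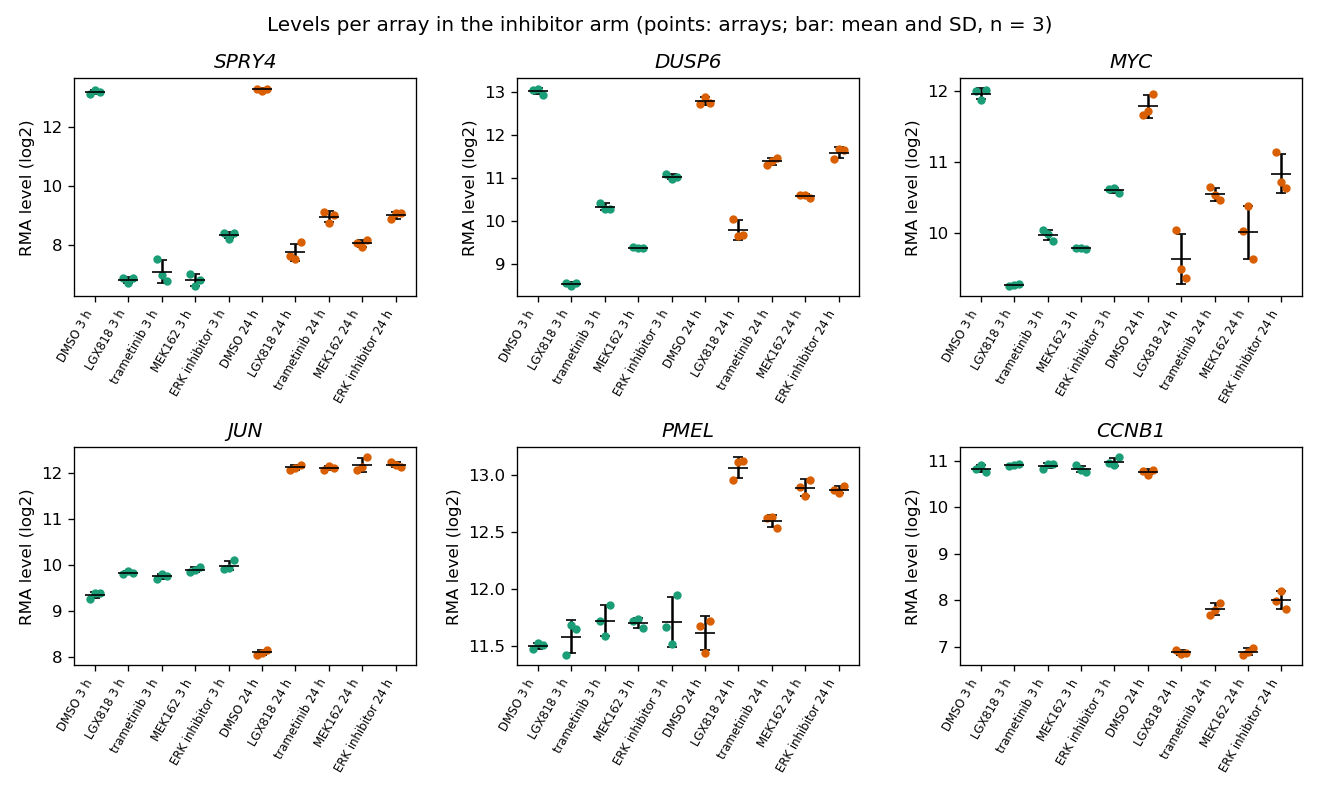
Expression of SPRY4, DUSP6, MYC, JUN, PMEL and CCNB1 (log2, y axis) under DMSO and each inhibitor (x axis), with 1 point per array, 3 h in green and 24 h in orange, and bars for the mean and SD of 3 arrays. SPRY4 and DUSP6 fell within 3 h, by 6.36 and 4.49 with LGX818, while JUN rose at 24 h, by 4.02 with LGX818.

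At 24 h the cells had lost most transcripts of DNA replication and mitosis under all inhibitors. NUF2, a kinetochore component, fell by 5.04, 3.48, 4.98 and 3.61 (SE 0.095). SPC25, of the same complex, fell by 5.53, 3.39, 5.09 and 3.55. The AP-1 factor JUN rose by 4.02, 4.02, 4.08 and 4.08 (SE 0.064; adjusted p = 2.37e-26, 9.25e-26, 2.06e-26 and 6.08e-26). The potassium channel KCNJ13 rose by 4.94, 3.53, 4.47 and 3.96 (SE 0.13), and CD36, which takes up fatty acids, by 3.88, 3.83, 3.99 and 3.75. EGR3 fell by 5.95, 5.15, 5.61 and 5.18 (SE 0.16).

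Further rises at 24 h were those of CCN5 (3.80, 3.09, 3.54 and 3.27), WIPF3 (3.70, 3.70, 3.94 and 3.32), and the autophagy gene MAP1LC3C (3.35, 3.78, 3.61 and 3.34). The WNT antagonist DKK1 rose by 2.71, 3.59, 3.04 and 3.70. Falls included CPN1 (-5.58, -4.64, -5.14 and -4.37), and SPRY4 (-5.52, -4.30, -5.21 and -4.26). The replication factor MCM10 (-5.04, -3.24, -4.58 and -3.18) and the ETS factor ETV5 (-4.45, -3.58, -4.72 and -3.53) also fell. DUSP6 fell by 3.00, 1.40, 2.21 and 1.20 (SE 0.081), CCND1 by 2.15, 1.12, 1.73 and 1.05 (SE 0.068) and MYC by 2.15, 1.24, 1.77 and 0.95 (SE 0.15). MITF fell with trametinib (-0.16, adjusted p = 0.0053) and the ERK inhibitor (-0.18, adjusted p = 0.00148) and did not pass with LGX818 (-0.0089, adjusted p = 0.878) or MEK162 (-0.024, adjusted p = 0.675). Counts were 3438, 3062, 3243 and 3265 genes up and 3278, 3198, 3276 and 3061 down.

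All 36 G2/M and mitosis genes fell with each inhibitor at 24 h (median -3.39, -2.64, -3.34 and -2.49; adjusted p = 0.00289, 0.00321, 0.00254 and 0.00308 with an estimated correlation). Of 34 G1/S and replication genes, 33, 34, 34 and 34 fell (median -2.60, -2.13, -2.61 and -2.05; adjusted p = 0.000616, 0.000761, 0.000525 and 0.0007 with an estimated correlation). Ribosome biogenesis genes fell in 31, 30, 32 and 31 of 32 (31, 31, 32 and 31 over the list alone), with LYAR at -1.44, -1.35, -1.43 and -1.32. MAPK activity genes fell in 8 of 9 each time (median -2.74, -1.15, -1.92 and -1.05). ERK feedback regulators fell in 8, 7, 8 and 7 of 9, a call that held for LGX818 and MEK162 and was lost for trametinib and the ERK inhibitor (adjusted p = 0.0584 and 0.0523 with an estimated correlation). Hypoxia genes fell in 14, 12, 15 and 13 of 19 and rose in 3 each time, with the carbonic anhydrase CA12 at -2.57, -2.39, -2.42 and -2.40 (adjusted p = 0.018, 0.00988, 0.0121 and 0.00974 with an estimated correlation).

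FOXO and PI3K-feedback genes rose in 14, 13, 14 and 16 of 20 at 24 h (15 and 14 over the list alone for LGX818 and trametinib), led by PIK3IP1, an inhibitor of PI3K (2.78, 2.48, 2.67 and 2.71), while IGF1R fell (-0.89, -0.65, -0.71 and -0.84). The call was lost for LGX818 (adjusted p = 0.0793 with an estimated correlation) and held for the others (adjusted p = 0.0412, 0.0352 and 0.0462 with an estimated correlation). Melanocyte genes rose in 13, 11, 11 and 11 of 17, with TRPM1 at 2.20, 1.77, 1.99 and 1.79 and TYRP1 at 1.79, 1.55, 1.68 and 1.64, while the melanocortin receptor MC1R fell (-0.65, -0.84, -0.79 and -0.72). The call was lost (adjusted p = 0.112, 0.239, 0.116 and 0.179 with an estimated correlation). Lysosome and autophagy genes rose in 25, 19, 22 and 20 of 29, with the protease CTSF at 1.34, 0.81, 1.04 and 1.22, fell in 2, 3, 2 and 2, with BNIP3 at -0.71, -0.76, -0.75 and -0.73, and lost their call (adjusted p = 0.189, 0.371, 0.257 and 0.221 with an estimated correlation). Antigen presentation genes rose in 14, 15, 14 and 14 of 19, with the peptide transporter TAP1 at 0.71, 0.61, 0.60 and 0.79, while TAP2 fell (-0.23, -0.38, -0.36 and -0.27), and lost theirs (adjusted p = 0.397, 0.375, 0.316 and 0.394 with an estimated correlation). Glycolysis genes were called down with trametinib (16 of 19 fell) and the ERK inhibitor (12 fell), with the glucose transporter SLC2A3 at -1.65 and -1.68, while 3 rose with each, led by TXNIP (1.21 and 1.01). Both calls were lost (adjusted p = 0.0669 and 0.105 with an estimated correlation).

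**Figure D2:**
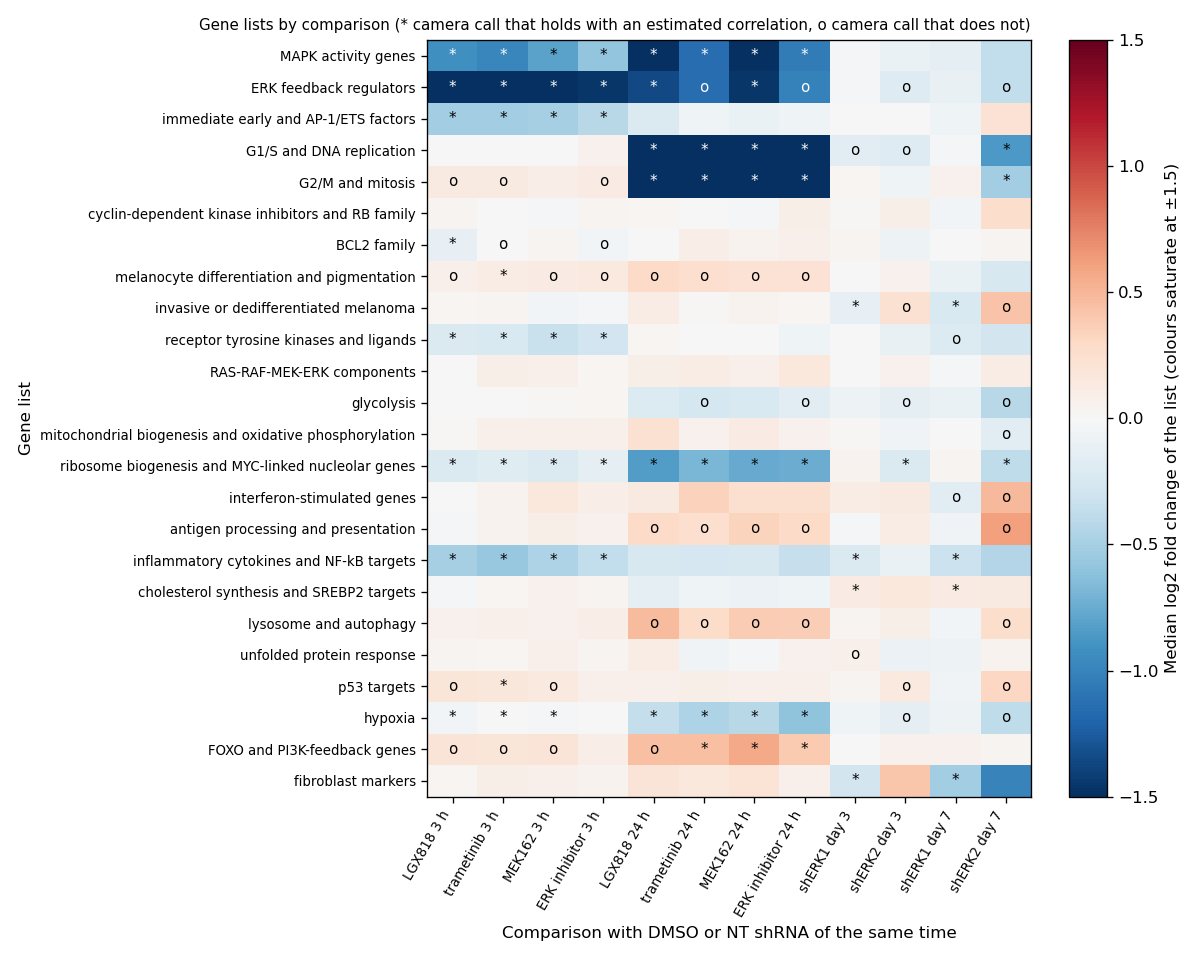
Median log2 fold change (colour, saturating at 1.5 either way) of 24 gene lists (y axis) in 12 comparisons with a control (x axis); an asterisk marks camera calls that held with an estimated correlation, and a circle those that did not. Cell cycle lists fell at 24 h with each inhibitor (G2/M median -3.39 with LGX818) and with the shRNA labelled shERK2 at day 7 (-0.52).

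The effect at 24 h differed from that at 3 h for 5047, 4819, 4935 and 4722 genes. For JUN it was higher by 3.54, 3.60, 3.53 and 3.44, for DKK1, which fell by 2.43 in DMSO cells between these times, by 3.28, 3.95, 3.77 and 3.64, and for CPN1 the differences were -5.27, -4.52, -5.09 and -4.21. The fall of DUSP6 was smaller at 24 h by 1.49, 1.29, 1.43 and 0.78 (SE 0.12), and that of SPRY4 by 0.84, 1.77, 1.15 and 0.58 (SE 0.21). CCND1 lost a further 1.59, 0.53, 1.09 and 0.46. For MITF, which had risen at 3 h, the differences were -0.48, -0.60, -0.50 and -0.55, while its level rose from 12.05 to 12.57 in DMSO cells and stood at 12.52 and 12.56 with LGX818. For MYC the difference passed with LGX818 (0.55, adjusted p = 0.0285) and trametinib (0.75, adjusted p = 0.00354) but not with MEK162 (0.41, adjusted p = 0.103) or the ERK inhibitor (0.42, adjusted p = 0.0984). The effect at 24 h was lower than that at 3 h for all 36 mitotic genes (median difference -3.55, -2.80, -3.49 and -2.71), which had not fallen at 3 h. It was also lower for 33, 33, 33 and 34 of 34 G1/S genes and 24, 24, 22 and 23 of 32 ribosome biogenesis genes, and these calls held with an estimated correlation. The feedback list was called up with trametinib and MEK162 (6 of 9 rose), and lost the call (adjusted p = 0.2 and 0.317 with an estimated correlation).

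At 3 h, 267 genes rose and 342 fell with all 4 inhibitors, ID2, SPRY4, DUSP6 and MYC among them, of 1842 changed by any, and 0 passed in opposite directions. At 24 h, 2548 rose and 2633 fell with all 4, JUN, CD36 and NUF2 among them, of 7750, with 35 in opposite directions. Independent lists of these sizes would share 0.0915 and 0.127 genes at 3 h and 122 and 115 at 24 h, and 20 simulated sets with no effect gave at most 0. Such sets hold no effect to share, so a count near 0 was fixed in advance and does not bear on likeness. Neither number models real effects measured against the same DMSO arrays. Fold changes of pairs of inhibitors correlated across genes at 0.855 to 0.916 at 3 h and 0.963 to 0.989 at 24 h, where shared DMSO arrays alone gave up to 0.501 in simulation. All inhibitors of one time were compared with the same 3 DMSO arrays, which adds to their likeness. The covariance of their fold changes was 0.0471 to 0.0616 at 3 h and 0.494 to 0.679 at 24 h, against 0.00516 and 0.00515 from shared controls alone in simulation. The spread between the DMSO arrays thus made up a small part of it. The simulation used the spread within groups, so it does not cover a deviation common to all 3 DMSO arrays of a time.

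Trametinib and MEK162, both MEK1/2 inhibitors, differed at 3 h in 4 genes. DUSP6 stood 0.95 higher (SE 0.081, adjusted p = 8.53e-08) and SPRY2 0.61 higher with trametinib (adjusted p = 0.000783), FRMD4A 0.29 higher and the stress gene DDIT4 0.25 lower (fold change -0.25, adjusted p = 0.014). SPRY4 (0.28, SE 0.15, adjusted p = 0.705) and MYC (0.19, SE 0.15, adjusted p = 0.872) did not pass. The ERK feedback list was higher with trametinib (2 of 9 rose, 4 over the list alone; adjusted p = 0.00334 with an estimated correlation). MAPK activity genes were also called higher (2 rose, 3 over the list alone), and lost the call (adjusted p = 0.0614 with an estimated correlation). The count was 1 when only both groups were fitted, 8 with all 54 arrays, and 2 and 10 without trametinib arrays a and b.

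At 24 h, 352 genes were higher and 93 lower with trametinib than with MEK162. The tachykinin precursor TAC1 was 1.89 higher (SE 0.22), SPC25 1.70, the nuclease EXO1 1.69, and RRM2, a ribonucleotide reductase subunit, 1.62 (SE 0.065). KCNJ13 (-0.94) and SERPINF1 (-0.91) were lower. Mitotic genes were higher in 31 of 36 (34 over the list alone; median 0.81; adjusted p = 1.47e-05 with an estimated correlation) and G1/S genes in 26 of 34 (30; median 0.46), that is, they had fallen less. MAPK activity and ERK feedback genes were each higher in 5 of 9 (7 and 6 over the list alone), and melanocyte genes lower in 4 of 17 (6; adjusted p = 0.0432 with an estimated correlation). Of the 445 genes, 370 (83.1%) had moved the same way from DMSO with both and less with trametinib, as had 58.5% of all tested genes, counted by sign and size whether or not they passed against DMSO. Without trametinib array c the count was 295.

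LGX818 at 3 h lowered DUSP6 by a further 1.32 (fold change -1.32, SE 0.071, adjusted p = 1.43e-12), SPRY2 by 0.94 and SPRY1 by 0.64 relative to the mean of both MEK inhibitors, while SPRY4 (-0.14, SE 0.13, adjusted p = 0.799) and MYC (-0.61, SE 0.13, adjusted p = 0.074) did not pass. In all 6 genes were lower and 0 higher. The ERK feedback list (3 of 9 lower, 4 over the list alone) and MAPK activity genes (2 and 4) were called lower (adjusted p = 0.00307 and 0.0135 with an estimated correlation). At 24 h, 411 genes were higher, among them KCNJ13 (0.94) and DAND5 (1.27), and 544 lower, among them TAC1 (-1.93, SE 0.19), ALDH1A1, an aldehyde dehydrogenase (-1.47), DUSP6 (-1.19) and CCND1 (-0.73). Mitotic genes were lower in 27 of 36 (32 over the list alone; median -0.47) and G1/S genes in 19 of 34 (22; median -0.28; adjusted p = 0.00225 with an estimated correlation for both). Against DMSO the medians with LGX818 (-3.39 and -2.60) lay next to those with MEK162 (-3.34 and -2.61), and those with trametinib (-2.64 and -2.13) made up the difference in both lists, whereas DUSP6 and CCND1 had fallen further with LGX818 than with either MEK inhibitor. The count of 955 was 550 without LGX818 array b.

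With the ERK inhibitor, pathway transcripts fell less at 3 h than with the MEK inhibitors. SPRY4 stood 1.38 higher (SE 0.13, adjusted p = 1.65e-07), DUSP6 1.18 (SE 0.071), MYC 0.72 and SPRY1 0.65, while ID2 was lower (-0.47). Of 9 ERK feedback genes 6 were higher (7 over the list alone; median 0.49; adjusted p = 6.07e-05 with an estimated correlation), and of 9 MAPK activity genes 4 (5; adjusted p = 0.000401 with an estimated correlation). At 24 h, TAC1 (1.43), the condensin subunit NCAPH (0.98), DUSP6 (0.60), SPRY4 (0.49), MYC (0.56) and CCND1 (0.38) were higher than the mean of both MEK inhibitors. Mitotic genes were higher in 31 of 36 (34; median 0.45) and G1/S genes in 25 of 34 (30; median 0.34; adjusted p = 0.000743 with an estimated correlation for both). MAPK activity genes were higher in 5 of 9 (7), and feedback genes in 4 (6), where the call was lost (adjusted p = 0.0647 with an estimated correlation). At 24 h most of the distance in the genes named was from MEK162. Against DMSO, the ERK inhibitor, trametinib and MEK162 stood at -4.26, -4.30 and -5.21 for SPRY4, -1.20, -1.40 and -2.21 for DUSP6 and -1.05, -1.12 and -1.73 for CCND1, with mitotic medians of -2.49, -2.64 and -3.34. The 43 genes at 3 h became 5 with only the groups compared and 28 with no level filter. They became 18 to 25 without any 1 of 6 arrays: ERK inhibitor a or c, MEK162 a or b, and trametinib a or c. The 481 genes at 24 h became 750 with the array letter as a replicate block, and 232 and 198 without ERK inhibitor arrays a and b.

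DMSO cells themselves changed between 3 h and 24 h, with 1586 genes up and 1457 down. The matricellular genes CCN1 and CCN2 fell (-2.85, SE 0.089, and -2.27), as did the chemokine CCL2 (-2.66) and DKK1 (-2.43), while PNRC1 (1.60, SE 0.082), YPEL2 (1.56), the connexin GJA5 (1.47) and MITF (0.52) rose. Immediate early factors fell in 21 of 29 (22 over the list alone; adjusted p = 8.50e-05 with an estimated correlation), ribosome biogenesis genes in 15 of 32 (17; adjusted p = 0.00848 with an estimated correlation) and inflammatory genes in 7 of 11 (adjusted p = 0.00618 with an estimated correlation). Calls were lost for several lists. Those up for interferon (12 of 19 rose), melanocyte (7), FOXO (9), hypoxia (9), cholesterol synthesis (6, with 7 over the list alone) and fibroblast (2 of 3) genes had adjusted p = 0.103, 0.0914, 0.0883, 0.0914, 0.148 and 0.0914 with an estimated correlation. Those down for invasive (7 fell, 8 over the list alone) and G1/S genes (4 fell) had adjusted p = 0.103 and 0.442 with an estimated correlation.

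The shRNA labelled shERK1 lowered its target, while the lists of ERK feedback and MAPK activity genes were not called on either day. MAPK3 fell by 1.54 at day 3 (SE 0.12, adjusted p = 3.24e-08; 8.16, SD 0.13, against 9.70, SD 0.064, with NT shRNA) and by 1.40 at day 7 (adjusted p = 7.45e-08). MMP2, a matrix metalloproteinase, fell by 1.57 at day 3 (SE 0.076) and 1.97 at day 7 (adjusted p = 2.07e-13). The chemokine CXCL8 fell by 0.74 and 1.37, and BMPER, a regulator of BMP signalling, rose by 1.62 (SE 0.20) and 1.95. Among the largest falls at day 3 were also COX7A2L (-1.30), PEX2 (-1.15) and NDUFA7 (-1.01). Against parental cells these stood at -1.36, -1.13 and -0.85. The series holds 1 labelled shRNA per target. For shERK1 and shERK2 alike, effects of lowering the target therefore cannot be told from other effects of the shRNA. DUSP6 fell at day 7 (-0.29, adjusted p = 0.00225), but did not pass there against parental cells (-0.15, adjusted p = 0.0659) or at day 3 (-0.20, adjusted p = 0.0861). At day 3 the feedback gene DUSP7 (-0.37, adjusted p = 0.00456), EGR3 (-0.42, adjusted p = 0.0229) and the pathway component RPS6KA2 (-0.69, adjusted p = 7.24e-06) fell. They passed against parental cells too (-0.22, -0.42 and -0.61). JUN rose against both controls (0.39 and 0.99). SPRY4 (-0.031 and 0.0040; adjusted p = 0.923 and 0.983), CCND1 (-0.10 and -0.13; adjusted p = 0.474 and 0.165), MYC (-0.37 and -0.15; adjusted p = 0.151 and 0.51) and MITF (0.034 and -0.015; adjusted p = 0.934 and 0.942) did not pass on either day. Against parental cells CCND1 fell on both (-0.38 and -0.45; adjusted p = 9.01e-05 and 5.52e-06), as it did in NT shRNA cells, and the falls of CXCL8 were -2.42 and -2.86. In all 193 genes rose and 263 fell at day 3, and 855 rose and 896 fell at day 7.

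With shERK1 the list of inflammatory genes fell, in 3 of 11 at day 3 (5 over the list alone) and 7 at day 7 (8), with CXCL1 at -1.46 at day 7 (adjusted p = 0.0048 and 0.00286 with an estimated correlation). Genes of invasive melanoma fell in 5 and 9 of 21 (7 and 11 over the list alone) and rose in 0 and 2, with the receptors NGFR (-0.74 and -1.34; -1.79 and -2.76 against parental cells) and AXL (-0.32 and -0.68; -0.81 and -1.19) among the falls (adjusted p = 0.0384 and 0.0194 with an estimated correlation). Cholesterol synthesis genes rose in 2 of 17 at day 3 (5) and 6 at day 7, with the synthase HMGCS1 at 0.50 and 0.63 (adjusted p = 0.0341 and 0.0458 with an estimated correlation), and at day 7 lost the call against parental cells (adjusted p = 0.0789). Of 3 fibroblast markers 2 and 3 fell, led by the matrix protein POSTN (-1.16 at day 3). The inflammatory and fibroblast lists were also lower in NT shRNA than in parental cells, and so was the invasive melanoma list at day 3. On day 3 and day 7 NGFR (-1.05 and -1.42) and AXL (-0.50 and -0.51) were lower there, while TWIST1 was higher (0.45 and 0.83). In the shERK1 arrays, genes that separate the controls were higher than with NT shRNA (DSP 8.27 against 7.85 at day 3 and 9.36 against 8.78 at day 7). Whether the falls with shERK1 share a source with the difference between the controls was not tested. G1/S genes fell in 5 of 34 at day 3 (8) and the list that includes the unfolded protein response rose in 4 of 23 (5). Both calls were lost (adjusted p = 0.0952 and 0.148 with an estimated correlation, and 0.336 for each against parental cells, where the latter list turned direction). At day 7 the calls down of receptor tyrosine kinases (6 of 15; 9 over the list alone) and interferon genes (6 of 20; 7) were lost (adjusted p = 0.213 and 0.403 with an estimated correlation).

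Several of the largest changes with shERK1 lay in genes that also separated the controls. SELENOP, a selenium carrier, rose by 1.45 at day 3 and 1.88 at day 7, and NELL2 by 1.37 and 1.81. Against parental cells at day 3 the rises of BMPER, SELENOP and NELL2 were 3.78, 4.09 and 3.22. That of MECOM, a zinc finger factor, was 2.00 at day 7 (SE 0.15) and 4.00 against parental cells. Over 44 genes at least 4-fold higher in NT shRNA than in parental cells on both days, the median of shERK1 minus NT shRNA was 0.73 at day 3 (38 of 44 above 0) and 1.16 at day 7 (43 of 44). The falls of MAPK3 (-1.41 and -1.23) and MMP2 (-1.80 and -2.29) stood against parental cells, while CD52 turned from -1.36 to 0.79 and TRPM1 from 0.48 to -0.076 at day 7. The counts of 456 and 1751 were 2072 and 3868 against parental cells (356 and 1478 alike against both controls), 222 and 994 without genes that differ between the controls, and 695 and 3218 with only the groups compared. They were 268, 291 and 240 at day 3 without NT shRNA array a, b or c, and 1067 and 1160 at day 7 without shERK1 array b or NT shRNA array c.

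With the shRNA labelled shERK2, 3204 genes rose and 3078 fell at day 7, after 1714 and 1511 at day 3. TAC1 rose by 2.64 and 5.85 (SE 0.21; 5.69 against parental cells at day 7) and the chemokine CCL18 by 3.09 and 5.11 (SE 0.15; 5.14). PLN, a regulator of the calcium pump, fell by 5.01 at day 7 (SE 0.096, adjusted p = 6.44e-20; -4.88 against parental cells). SPRY1 fell by 1.38 and 2.84, SPRY4 by 0.53 and 0.72 (SE 0.079) and DUSP6 by 0.40 and 0.62 (SE 0.063). MITF fell at day 7 (-0.89, SE 0.094, adjusted p = 5.46e-08) and not at day 3 (-0.22, adjusted p = 0.0741), whereas MAPK3 (-0.016 and 0.050; adjusted p = 0.939 and 0.728), CCND1 (-0.084 and 0.12; adjusted p = 0.33 and 0.11, but -0.37 and -0.21 with adjusted p = 0.000117 and 0.00746 against parental cells) and MYC (-0.048 and -0.26; adjusted p = 0.824 and 0.0988) did not pass.

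Other rises with shERK2 were those of GPR83 (1.99 and 4.28), the membrane proteins SLITRK6 (2.01 and 3.96; 1.02 and 3.02 against parental cells) and MAL (3.06 and 3.62), CD36 (1.98 and 3.67) and OLFML2A (2.30 and 3.52). At day 7, RBM24, an RNA-binding protein (3.83), and CD53 (3.71) rose. The phospholipase PLA1A fell by 4.79 at day 7. The connexin GJA1 (-6.45 and -5.83), LIN28B, which blocks let-7 maturation (-6.12 and -6.26), and SHISA2 (-5.95 and -5.85) fell against NT shRNA. So did the neuronal hydrolase UCHL1 (-5.32 and -5.76), the neurofilament NEFL (-4.39 and -4.98) and SALL1 (-3.70 and -4.55). In shERK2 cells at day 3 these 6 stood at 3.59, 4.20, 3.43, 4.25, 3.62 and 3.50, levels that can be background, so the falls are lower bounds. Against parental cells at day 3, GJA1 stood at 0.12, LIN28B at -0.017, SHISA2 at -0.76 and UCHL1 at 0.099. Over the 44 genes that separate the controls, the median of shERK2 minus parental was -0.00548 at day 3. Of the 3225 genes at day 3, 1856 changed alike against both controls and 45 in opposite directions, and at day 7 4961 of 6282 alike and 91 opposite. The count at day 3 was 5127 with only the groups compared and 2135 without genes that differ between the controls, and that at day 7 was 4147 with only the groups compared.

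Ribosome biogenesis genes fell with shERK2 in 18 and 26 of 32 at day 3 and day 7 (19 and 27 over the list alone), with WDR12 at -1.40 at day 3 (adjusted p = 0.0218 and 0.0177 with an estimated correlation). At day 7, 33 of 34 G1/S genes fell, with GINS1, of the replication fork, at -1.54 (adjusted p = 0.0364 with an estimated correlation), and 32 of 36 mitotic genes, with the kinase AURKB at -1.03 (median -0.52; adjusted p = 0.0442 with an estimated correlation). The mitotic call was lost without array a (adjusted p = 0.128 with an estimated correlation), although 35 of 36 then fell with a median of -0.57. The GAPDH 3' minus 5' signal of that array was 1.53, against 0.163 to 0.320 in controls. At day 3, 14 of 34 G1/S genes fell (18), and that call was lost (adjusted p = 0.267 with an estimated correlation). ERK feedback genes fell in 5 and 6 of 9, with DUSP5 at -1.03 and -0.94, and both calls were lost (adjusted p = 0.267 and 0.253 with an estimated correlation).

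Further lists were called with shERK2 and lost with an estimated correlation. Invasive melanoma genes rose in 12 and 13 of 21 and fell in 3 and 5, with NGFR at 1.86 and 3.34 (0.81 and 1.92 against parental cells) and the ligand WNT5A at -2.13 and -1.81 (-1.96 and -0.77) (adjusted p = 0.267 and 0.173 with an estimated correlation, and 0.944 and 0.0777 against parental cells). Glycolysis genes fell in 6 and 14 of 20, with SLC2A3 at -1.78 and -3.24 (adjusted p = 0.267 and 0.102 with an estimated correlation), and hypoxia genes in 6 and 10 of 19, with CA12 at -0.88 and -1.72 (adjusted p = 0.267 and 0.106 with an estimated correlation). The p53 targets rose in 9 and 14 of 21, with TP53INP1 at 1.15 at day 7 while GDF15 fell (-0.84 and -1.75; adjusted p = 0.298 and 0.229 with an estimated correlation, and 0.126 and 0.0749 against parental cells). At day 7, antigen presentation genes rose in 15 of 18 (16 over the list alone), with HLA-DRB1 at 1.65 (adjusted p = 0.229 with an estimated correlation). Interferon genes rose in 11 of 20, with the effector MX2 at 1.65 (adjusted p = 0.498 with an estimated correlation). On the same day lysosome genes rose in 20 of 29, with CTSF at 0.98 (adjusted p = 0.509 with an estimated correlation, 0.131 against parental cells and 0.0765 without array a). Genes of mitochondrial biogenesis and oxidative phosphorylation fell in 13 of 27, with the mitochondrial DNA factor TFAM at -1.38. Cytochrome c (CYCS) rose by 1.18 (0.62 against parental cells). The list had adjusted p = 0.349 with an estimated correlation, and 0.0687 against parental cells.

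**Figure D3:**
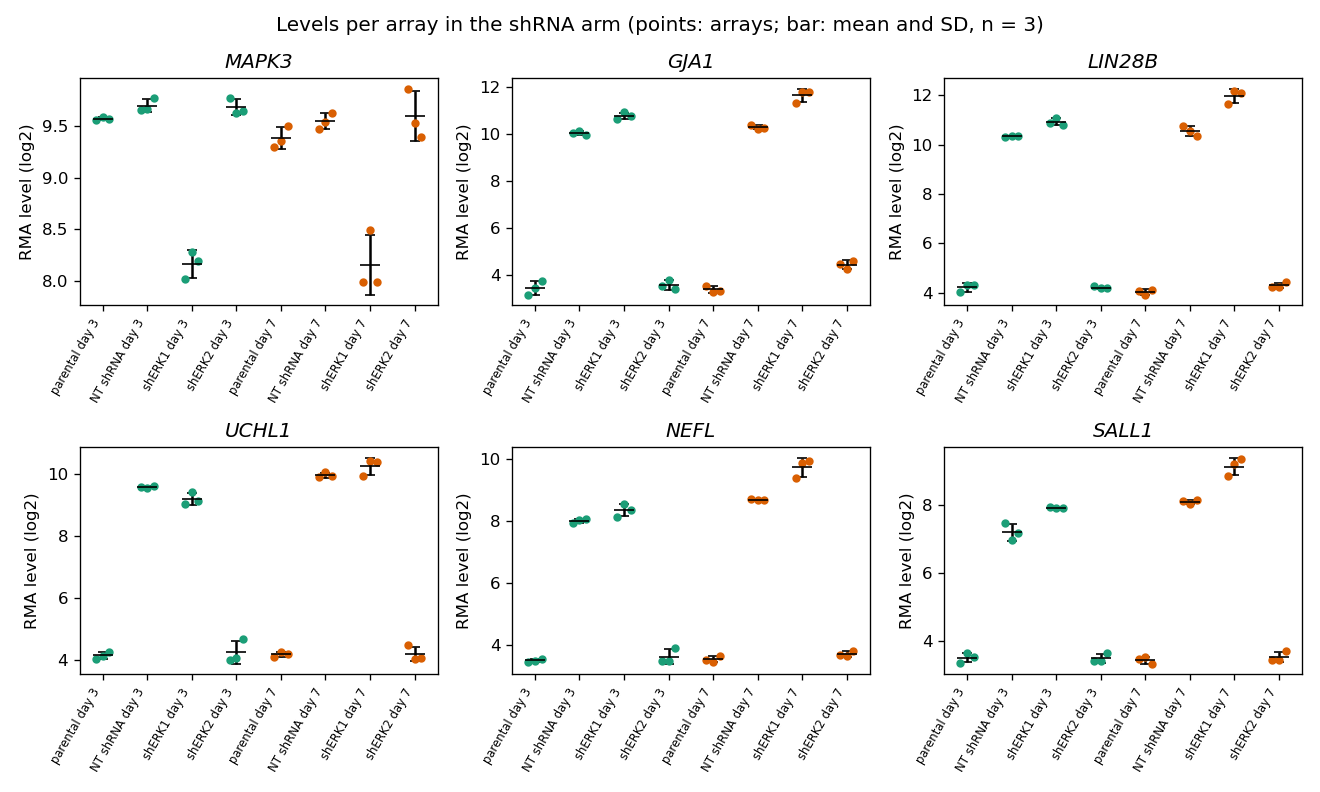
Expression of MAPK3, GJA1, LIN28B, UCHL1, NEFL and SALL1 (log2, y axis) in parental, NT shRNA, shERK1 and shERK2 cells (x axis), with 1 point per array, day 3 in green and day 7 in orange, and bars for the mean and SD of 3 arrays. MAPK3 was lower with shERK1 (by 1.54 at day 3), and GJA1 was high with NT shRNA and shERK1 and low in parental and shERK2 cells (NT minus parental 6.57 at day 3).

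Compared directly, shERK2 and shERK1 cells differed in 1850 genes up and 1621 down at day 3 and in 3480 and 3234 at day 7. MAPK3 was 1.53 higher with shERK2 at day 3 (SE 0.12, adjusted p = 1.18e-09), NGFR 2.60 and 4.68 higher at day 3 and day 7, and TAC1 2.65 and 6.65. GJA1 was lower (-7.18 and -7.17), and so were SPRY4 (-0.49 and -0.72) and DUSP6 (-0.21 and -0.33). Ribosome biogenesis genes were lower in 23 and 26 of 32 (25 over the list alone at day 3; adjusted p = 0.008 and 0.0185 with an estimated correlation), and at day 7 so were 33 of 34 G1/S and 31 of 36 mitotic genes (adjusted p = 0.0491 with an estimated correlation for both). Invasive melanoma genes were higher in 13 and 16 of 21, a call lost on both days (adjusted p = 0.0949 and 0.0683 with an estimated correlation). Also lost at day 7 were calls up of antigen presentation (15 genes higher), interferon (15) and p53 (16) lists (adjusted p = 0.253, 0.362 and 0.193 with an estimated correlation). The effects of both shRNAs, which share the NT arrays, correlated across genes at -0.0814 at day 3 and -0.249 at day 7, against 0.501 in simulation from shared controls alone. Over the 44 genes that separate the controls, shERK1 stood above NT shRNA (median 0.73 and 1.16), while shERK2 stood near parental cells (median of shERK2 minus parental -0.00548 and 0.14). This correlation was not repeated without such genes, so how far its sign rests on them is not known.

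Between day 3 and day 7 the effect of shERK2 changed for 1070 genes up and 1272 down, and that of shERK1 for 29 and 22. TAC1 gained 3.21 with shERK2, the nuclear export factor NXF3 2.96 and RBM24 2.52, while the effect was lower at day 7 for PLA1A (-3.21), SERPINF1 (-2.76), PLN (-2.64) and MITF (-0.66, adjusted p = 0.000904). It was lower too for 31 of 34 G1/S genes (32 over the list alone) and 29 of 36 mitotic genes (adjusted p = 0.00831 with an estimated correlation for both). With shERK1 the chemokine receptor CXCR4 gained 2.01 and MECOM 1.28, and the effect on DKK1 was lower at day 7 (-0.91). CXCR4 belongs to the 44 genes that separate the controls. Over these genes the median change from day 3 to day 7 was 1.10 in shERK1 and 0.61 in NT shRNA cells. Whether the gains with shERK1 share a source with the difference between the controls was not tested. The 51 genes with shERK1 became 6 to 30 without any 1 of shERK1 day 3 array c, NT shRNA day 3 array a or c, shERK1 day 7 array b or c, and NT shRNA day 7 array a, b or c. They became 184 without shERK1 day 7 array a, 303 with only the groups compared, 155 with all 54 arrays, 109 with no level filter and 79 with centred arrays.

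**Figure D4:**
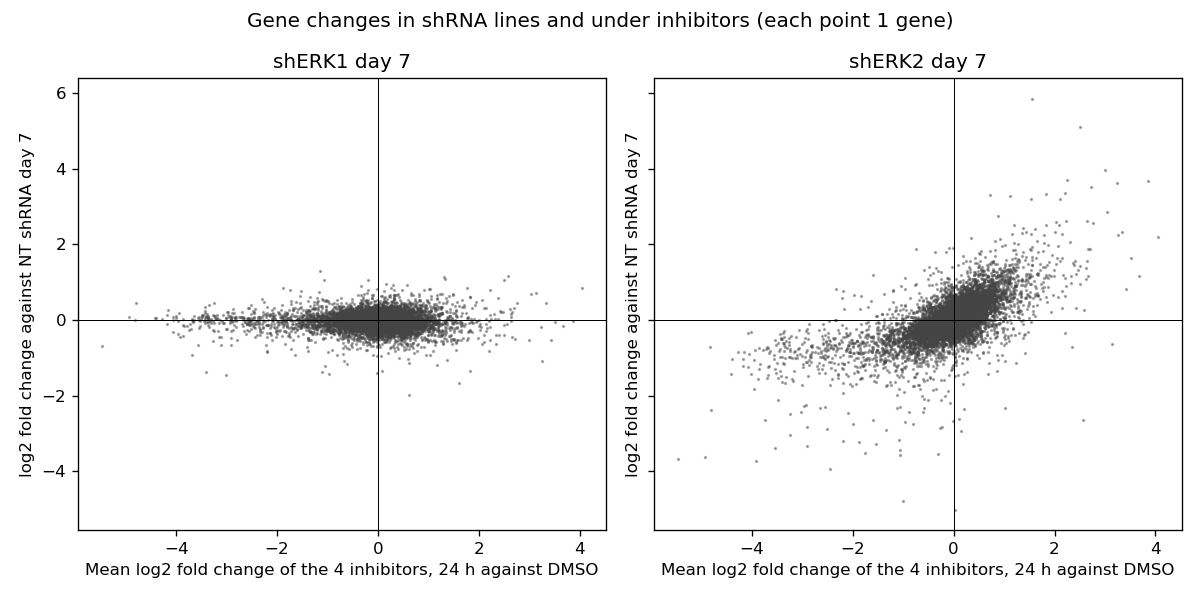
Log2 fold change against NT shRNA at day 7 (y axis) for shERK1 and shERK2 (panels), against the mean log2 fold change of the 4 inhibitors at 24 h (x axis), with 1 point per gene for 9456 genes. The points follow a rising band for shERK2 (r = 0.656) and form none for shERK1 (r = 0.00119).

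Across the 9456 genes tested in both arms, the effect of shERK2 correlated with the mean effect of the inhibitors at 24 h at 0.557 at day 3 (single arrays 0.539, 0.545 and 0.547) and 0.656 at day 7 (0.553, 0.658 and 0.656). CD36, MAL, TRPM1 and JUN lay high and EGR3 and SPRY1 low in both effects at day 3. For shERK1 the correlation was 0.147 at day 3 (single arrays 0.131, 0.149 and 0.0853) and 0.00119 at day 7 (0.0341, 0.00236 and -0.0287). Against parental cells these values were 0.475 and 0.634 for shERK2 and -0.0197 and -0.0830 for shERK1, so the sign for shERK1 over all genes depended on the control. Over the 7784 genes that do not differ between the controls, shERK1 gave 0.146 and 0.00634 against NT shRNA and 0.0195 and -0.0616 against parental cells, so at day 3 the sign did not turn.

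NT shRNA and parental cells differed in 594 genes up and 574 down at day 3 and 809 and 793 at day 7. GJA1 was higher with NT shRNA by 6.57 (SE 0.15) and 6.88, LIN28B by 6.11 (SE 0.13) and 6.52, UCHL1 by 5.42 and 5.77, and the neuronal gene BEX5 by 5.12 and 5.90. In parental cells at day 3 these stood at 3.47, 4.22, 4.15 and 4.38, levels that can be background, so the differences are lower bounds. FGL2 (-3.18 and -2.84) and CCL2 (-2.39 and -2.44) were lower, and so was CCND1 (-0.28 and -0.32). Inflammatory genes were lower in 5 and 6 of 11 (adjusted p = 0.0216 with an estimated correlation on both days) and all 3 fibroblast markers on both days (adjusted p = 0.0216 and 0.0412 with an estimated correlation). Ribosome biogenesis genes were higher in 8 of 32 on both days, a call held at day 3 and lost at day 7 (adjusted p = 0.0245 and 0.0529 with an estimated correlation). The invasive melanoma list and the list that includes the unfolded protein response were lower at day 3 and lost at day 7 (adjusted p = 0.183 and 0.0971 with an estimated correlation). DSP, an epithelial desmosome gene, stood at 4.47 in parental, 7.85 in NT shRNA, 8.27 in shERK1 and 4.46 in shERK2 cells at day 3. Of the leukocyte markers only CD68 passed the level filter, and it rose with shERK2 at day 7 (0.83). The count at day 3 was 2623 with only the groups compared.

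From day 3 to day 7, 247 genes rose and 291 fell in NT shRNA cells. The protease PRSS33 (1.59), TUSC1 (1.40), BPI (1.34) and ZNF711 (1.24) rose, and RASGRP3, a RAS activator (-1.12), and the receptor VIPR1 (-1.04) fell. Over the 44 genes that separate the controls, the median change was 0.61 in NT shRNA cells (42 above 0). In parental cells, where their levels can be background, it was -0.082 (12 above 0). G1/S genes rose in 11 of 34 (20 over the list alone) and ribosome biogenesis genes in 4 of 32 (11; adjusted p = 0.0451 with an estimated correlation for both). The count of 538 was 2467 with only both groups fitted, and 213 to 305 without any NT shRNA array except day 7 array b.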

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

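The tests in this part, other splits of the arrays among them, were chosen only after the results were seen.

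The effect at 24 h differed from that at 3 h for 5047 genes with LGX818, 4819 with trametinib, 4935 with MEK162 and 4722 with the ERK inhibitor, JUN and the mitotic genes among them. Of 100 splits of the arrays concerned, 6, 5, 7 and 6 gave as many genes, the real split included, with 6171, 5178, 5491 and 5831 genes at most in another split. This count did not exclude chance, but it cannot decide the question. Each of the 5, 4, 6 and 5 other splits as large kept the arrays of 24 h apart by treatment, and such a split leaves the effect at 24 h in the comparison. The effect at day 7 differed from that at day 3 for 51 genes with shERK1 and 2342 with shERK2. Here 7 and 9 of 100 splits gave as many, with 1947 and 5057 genes at most in another split, and 6 of 6 and 7 of 8 other splits as large kept the arrays of day 7 apart in the same way.

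The GAPDH 3' minus 5' signal was 1.53 in array a and 0.565 in array c of shERK2 at day 7, 0.707 in array c of the ERK inhibitor at 3 h and 0.470 in array a of LGX818 at 24 h, against 0.163 to 0.320 in the arrays of control groups. These 4 arrays lay above every control array in the same measure for ACTB too, which ran from 0.948 to 1.46 in controls. Further arrays lay above every control array in GAPDH alone. At 24 h these were ERK inhibitor arrays a (0.530) and b (0.372), LGX818 array b (0.333) and MEK162 array b (0.330). The others were LGX818 array c at 3 h (0.358) and shERK2 array a at day 3 (0.324). With 3 arrays per group, single arrays were not tested as outliers.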

How the results depend on the processing

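Tests without genes that differ between the controls, counts of genes alike against both controls, and list tests against parental cells or without single arrays were chosen only after the results were seen.

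Requiring a log2 fold change of at least 1 lowered every count, by construction: 89, 72, 89 and 51 genes with LGX818, trametinib, MEK162 and the ERK inhibitor at 3 h, 1297, 1081, 1213 and 1070 at 24 h, and 1067, 927, 999 and 899 for the difference of both times. It left 47 and 914 genes alike with all 4 inhibitors at 3 h and 24 h. For trametinib against MEK162, LGX818 against the MEK inhibitors and the ERK inhibitor against them, it left 0, 1 and 2 genes at 3 h and 48, 20 and 6 at 24 h, and for DMSO over time 72. In the shRNA arm it left 28 (shERK1 day 3), 104 (shERK1 day 7), 277 (shERK2 day 3), 837 (shERK2 day 7), 295 and 1078 (shERK2 against shERK1), 5 and 214 (effects of shERK1 and shERK2 over time), 158 and 186 (NT shRNA against parental) and 11 (NT shRNA over time).

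Fitting only the groups compared changed the count for the ERK inhibitor at 3 h to 295, trametinib against MEK162 at 3 h to 1, the ERK inhibitor against MEK inhibitors at 3 h to 5, shERK1 to 695 and 3218, shERK2 to 5127 and 4147, the shERK1 effect over time to 303, NT shRNA against parental at day 3 to 2623 and NT shRNA over time to 2467. A fit of all 54 arrays gave 8 genes for trametinib against MEK162 at 3 h and 155 for the shERK1 effect over time. With no level filter the ERK inhibitor and the MEK inhibitors differed at 3 h in 28 genes and the shERK1 effect over time in 109, and the correlation of shERK2 with the inhibitors was 0.400 at day 3 and 0.543 at day 7. With arrays centred on their median, the shERK1 effect over time had 79 genes. The array letter as a replicate block moved 1 of 28 counts, that of the ERK inhibitor against MEK inhibitors at 24 h, from 481 to 750. The cause of these changes was not tested.

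With parental cells as control, shERK1 changed 2072 and 3868 genes, its correlation with the inhibitors was -0.0197 at day 3, reversed (0.0195, not reversed, without genes that differ between the controls), and -0.0830 at day 7, and that of shERK2 was 0.475 at day 3. Without genes that differ between the controls, shERK1 changed 222 and 994 genes and shERK2 2135 at day 3, with a correlation of 0.523, and 1856 genes changed alike with shERK2 at day 3 against both controls. Against parental cells these log2 fold changes reversed: ISG20 (0.14 and 0.056 with shERK1 at day 3 and day 7), CD52 (0.79), TRPM1 (-0.076) and GPR143 (0.27) with shERK1 at day 7, and with shERK2 at day 3 GJA1 (0.12), UCHL1 (0.099), SLAIN1 (0.18), NEFL (0.13), FAM171A1 (0.0058), FGFR3 (0.12), CCL2 (-1.08), DEPP1 (0.14) and POSTN (-0.80). With shERK2 at day 7 these were LIN28B (0.27), GJA1 (1.05), UCHL1 (0.011), NEFL (0.18), SLAIN1 (0.34), SALL1 (0.091), DSP (0.31) and CCND1 (-0.21). In shERK2 and parental cells at day 3, levels that can be background were those of GJA1 (3.59 and 3.47), UCHL1 (4.25 and 4.15), NEFL (3.62 and 3.49), SLAIN1 (3.79 and 3.61) and FAM171A1 (4.31 in both). The turned sign of such genes is not read as a reversed effect. The list that includes the unfolded protein response also turned with shERK1 at day 3 (adjusted p = 0.336).

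Leaving out 1 array gave 629 to 1381 genes for the ERK inhibitor at 3 h, 721 to 1300 for trametinib at 3 h, 2 to 10 and 295 to 439 for trametinib against MEK162 at 3 h and 24 h, 550 to 953 for LGX818 against MEK inhibitors at 24 h, and 18 to 54 and 198 to 569 for the ERK inhibitor against them. For shERK1 it gave 240 to 361 at day 3, 1067 to 1583 at day 7 and 6 to 184 over time, for NT shRNA over time 213 to 455, and a correlation of 0.547 to 0.562 for shERK2 at day 3. Over 15107 gene values under alternatives, the sign turned in 22 that passed in either setting, the call was lost in 611 and gained in 26. In another 65 the sign turned without a call in either setting, and these were not counted as reversed, a choice made after seeing them. Of 116 list calls, 67 held with an estimated correlation and 115 with fry.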

Other observations

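The tests of explanations in this part, and the list of marker genes used in them, were chosen only after the results were seen.

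Several lists that were not called at 24 h held large changes in both directions. Of 29 immediate early factors, 9, 9, 9 and 10 rose and 14, 14, 13 and 14 fell with LGX818, trametinib, MEK162 and the ERK inhibitor (adjusted p = 0.237, 0.413, 0.336 and 0.547), with CCN1 at 2.46, 2.70, 2.59 and 2.84 beside the fall of EGR3. In the BCL2 family, pro-apoptotic BMF rose (2.61, 2.40, 2.32 and 2.36) and PMAIP1 fell with all 4 (from -3.82 with LGX818 to -2.88 with the ERK inhibitor). Among genes of invasive melanoma, the repressor ZEB2 rose (2.26, 2.18, 2.04 and 2.09), and its relative ZEB1 fell (-1.74, -1.43, -1.61 and -1.38). The folate enzyme MTHFD2, a member of the list that includes the unfolded protein response, fell by 2.74, 2.12, 2.79 and 2.09. The antiviral gene MX2 rose by 2.15, 2.05, 2.05 and 1.96, and CCL2 rose by 1.76, 2.47, 2.01 and 2.20. In DMSO cells CCN1 fell by 2.85 between 3 h and 24 h, and CCL2 fell too. The rises of both are therefore against lowered control levels.

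Components of the pathway itself changed as well. RPS6KA1, a kinase downstream of ERK, fell at 24 h by 0.84, 1.11, 1.09 and 0.85, and the small GTPase HRAS by 0.65, 0.52, 0.49 and 0.46. Of 16 such components 8, 7, 7 and 8 rose and 2 fell with each inhibitor (adjusted p = 0.426, 0.373, 0.387 and 0.254). Of 5 cyclin-dependent kinase inhibitors and RB family genes, CDKN1B rose (0.57, 0.43, 0.54 and 0.50) and CDKN1C fell (-0.57, -0.57, -0.57 and -0.53), and the list was not called (adjusted p = 0.99, 0.943, 0.942 and 0.885).

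A group of 44 genes, GJA1, LIN28B, UCHL1 and NEFL among them, was higher in NT shRNA than in parental cells by a median of 2.68 log2 at day 3 and 3.45 at day 7, and higher still with shERK1 (3.62 and 4.77). A response to vector and doxycycline shared by all lines is argued against by the median of shERK2 minus parental at day 3 (-0.00548, 20 of 44 genes above 0). At day 7 that median was 0.14, with 35 of 44 above 0. A response that is absent with the shRNA labelled shERK2 was not tested. From day 3 to day 7 the group gained 0.747 more in NT shRNA than in parental cells. Parental levels can be background (median 4.21 log2 at day 3), where a change with time shared by both would not show. This gain therefore does not decide on a fixed difference between sublines. As a hypothesis, cells of the HEK293 type may have been mixed in: of 42 marker genes 38 were measured, and of 16 tested outside the group 10 had risen in NT shRNA at day 7, against a median of 1 and at most 6 in 10000 random lists. None of these lists reached 10, so the share is given as 0.01%, the smallest they can give. The marker list, 7 of whose genes lie in the group, was chosen after the group was seen. The share therefore cannot tell HEK293 cells from another source of such genes. Of 15 list genes that were brighter in parental cells 4 rose, ZIC2 (2.14), CKB (1.40), IGF2BP1 (0.63) and TUBB2B (0.61), and 11 did not pass, among them MAP1B (-0.27), CDH2 (0.043), TFAP2A (-0.035), VIM (0.014) and KRT10 (0.13); of the dimmer ones tested, BEX1 (0.18), STMN2 (0.048), PAX2 (-0.037), ELAVL4 (-0.049), LHX1 (-0.23) and HOXC8 (0.049) did not pass, and INA, which rose by 1.81, stood at 7.12 in shERK2 cells, where the group is low.

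With shERK2 at day 7, 6282 genes changed, and array a had a raised 3' to 5' signal. Without it 6359 changed, which argues against degraded RNA in that array as the source of the count. Array c of the group, whose signal was raised less (0.565), remained in that fit. Without c in place of a 6045 changed, and a fit without both was not made. The highest count with 1 array left out, 6695, came without array b, whose signal was 0.272. That fit keeps both arrays of raised signal, so a part of the count due to both is left open. The call of mitotic genes, however, was lost without array a (adjusted p = 0.128 with an estimated correlation), although the fall did not shrink: the median was -0.57 without the array and -0.52 with it, and 35 and 32 of 36 fell. The correlation estimated between these genes was 0.222 without it and 0.135 with it.

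Trametinib and MEK162 differed at 24 h in 445 genes, of which 83.1% had moved the same way with both and less with trametinib. A smaller effect of trametinib at the dose used is a candidate explanation, but 1 dose of each was measured, so dose and compound cannot be told apart. RNA quality is argued against, as 0 of 6 arrays lay above every control array in both 3' to 5' signals. In GAPDH alone, MEK162 array b lay slightly above them (0.330, against at most 0.320).

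For other counts the arrays were also split in other ways. With 3 arrays against 3, 1 of 10 splits, the real one, gave as many genes in every comparison, and 10 splits are too few for a share under 0.05. The highest count of another split was 0, except 1 for LGX818 at 24 h (6716 in the real split), 1 for trametinib against MEK162 at 24 h (445), 260 for shERK2 at day 7 (6282) and 29 for shERK2 against shERK1 at day 7 (6714). For genes changed alike by all 4 inhibitors, 1 of 100 splits, the real one, gave as many (609 and 5181 real, 0 in any other). For LGX818 against the MEK inhibitors, 1 of 100 did so too (6 and 955 real, 2 and 536 at most otherwise). A random grouping of the arrays thus gave as many in under 0.05 of the splits. Other splits mix arrays of different treatments, which by itself lowers the count of a strong effect. They do not cover a deviation common to all 3 arrays of a group. For the ERK inhibitor against the MEK inhibitors, 2 of 100 splits gave as many genes at both times (43 and 481 real). That share lies under 0.05, but each time a split other than the real one gave more genes, so a random grouping is not set aside here. The larger split at 3 h gave 2216 genes, by setting array c of the ERK inhibitor, MEK162 and trametinib apart, which points to a structure by array letter. The larger split at 24 h gave 685, by setting MEK162 apart from the other arrays. With the letter as a replicate block the counts were 50 and 750.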
